A study of Drosophila melanogaster with 3 samples.

How the data were processed

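The samples were 3 biological replicates of chromatin immunoprecipitation with sequencing (ChIP-seq) on whole Drosophila melanogaster prepupae, males and females pooled, that carried the protein CG10669 with a green fluorescent protein (GFP) tag at its C-terminus. Replicate numbers came from the labels, and all 3 replicates formed 1 group without a treated or untreated counterpart. The labels gave sonication with a size range of 200 to 800 bp as the fragmentation. The sample descriptions used the words for an input control, while the assay, the antibody field and the peak files belong to an immunoprecipitation, and the files were treated as such. The antibody label names CG10669 while the line carries a GFP fusion, so it is unclear whether only the tagged protein or the untagged one as well was recovered. The age label of 24 days does not match a prepupa and was not used.

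Each replicate had a list of 30000 candidate peaks, a pooled list held 30000 more, and a reproducible list held 7248. Per the file headers, the authors made each replicate's list from that replicate's alignments and a control file shared by all 3 replicates, as input for the irreproducible discovery rate (IDR) procedure. Per the file headers, the pooled list came from the pooled alignments of the 3 replicates and the reproducible list from the IDR step, all in dm6 coordinates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal of a peak is the caller's own value, on a different scale in each list. Signals were therefore compared only within a list, as ranks or after division by the median candidate signal of the same list. The deposited −log10 q-value of each peak was tied at its list's maximum of 4.24 for all 7248 reproducible peaks, so it was described and not used for ranking. The summit position within each peak was used for all distances. The reproducible peaks were exactly the 7248 pooled candidates with the highest signal, which was checked on the files. Total read numbers are not given in the sources used here, so sequencing depth was unknown and the intervals given below cover counting error over peaks or genes only.

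For each replicate, the 7248 candidates with the highest signal formed a list of the same length as the reproducible list. Values computed in these 3 replicate lists gave the mean and standard deviation (SD) with n = 3, and the 7248 pooled candidates with the lowest signal served as a low-signal comparison. Replicates shared the control file, so part of their overlap may come from it. A reproducible peak counted as recovered in a replicate if a summit of that replicate's list lay within 200 bp. Chance was taken from 1000 circular shifts of the summits along each chromosome (200 shifts for pairs of replicates and for annotation classes), with two-sided permutation p-values, and the smallest value these can give is 0.002 for 1000 shifts and 0.01 for 200. Genes came from Ensembl release 115, whose chromosome lengths hold every peak, on the 6 chromosomes 2L, 2R, 3L, 3R, 4 and X, with 13945 protein-coding genes, and 5809 transposable element features were left out of the genes. A promoter peak had its summit within 500 bp of an annotated transcription start site (TSS) of a protein-coding gene, and a gene counted as bound if a reproducible summit lay within 500 bp of any of its TSSs. Other summits were classed in the order 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic.

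Promoter and distal signals were compared by a two-sided permutation test of the ratio of medians with 100000 resamples, whose smallest p-value is 1e-05. Chromosome shares were compared with chromosome length by an exact two-sided binomial test. For 26 gene lists, the bound members were compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists at 0.05. Transfer RNA genes were compared with all other annotated genes, and the other lists with protein-coding genes. Head-to-head gene pairs had TSSs on opposite strands at most 1000 bp apart without overlap. For 23 consensus motifs, the 200 bp window at the summit was compared with 1 of its 2 flanking windows centred 500 bp away, drawn at random, by an exact two-sided binomial test of the windows that differed, adjusted over the 23 motifs. The same test was run on all 7-mers. Intervals of shares were 95% Wilson intervals, and a count of 0 was given the upper limit of 3 counts. Peaks and genes are not biological replicates, so these tests describe the lists and the replicate SD gives the biological spread.

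The tests on recovery, promoters, chromosomes, gene lists, gene pairs and motifs, the lists themselves, the rule for named genes and 42 alternatives were fixed before the data were examined, and 5 alternatives were added afterwards. The text names the genes nearest to the 25 reproducible peaks of highest signal that were recovered in all 3 replicates, up to 4 bound members of each list by signal, CG10669, and 5 peaks more than 5 kb from any TSS. Members of multi-copy families (tRNA and histone genes) were treated as uncertain. For a named peak, its relative signal is the signal divided by the median candidate signal of the same replicate, as mean ± SD over 3 replicates. A 16 bp sequence element was learned on the 3624 odd-ranked reproducible peaks, and counted in the 3624 even-ranked peaks. Its starting word, CACTGA, was picked from 7-mer counts over all peaks, even-ranked ones included, so the count in even-ranked peaks is not fully independent of that choice. The alternatives covered distances, TSS windows, a stricter peak set, motif controls, the background of the gene lists and leaving out each replicate. For promoters, chromosomes, gene lists, gene pairs and motifs, a set without a replicate held the reproducible peaks recovered in both other replicates. Those peaks were still called from the pooled reads of all 3 replicates.

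On simulated data, the gene list test found 10 of 10 lists raised from 15 to 40% bound and called 0 of 10 unchanged lists among 13945 genes. The simulated lists were larger than most of the 26 lists tested, so a rise of this size can be missed in the smaller lists. The shift test found 10 of 10 sets of 1000 summits enriched at TSSs and called 0 of 10 random sets, with 200 shifts. The motif test on 2000 pairs of windows found 9 of 10 motifs planted in 5% of the windows, missing GAGA, and called 1 of 10 motifs that had not been planted, Pho. A share of 10% was then tried because GAGA had been missed, and it gave 10 of 10 found and again 1 of 10 called. Both simulations left out 3 motifs whose sequences are contained in others, a choice made after an earlier simulation had called BEAF-32 and the nuclear receptor motif. Small changes of frequent motifs can therefore be missed, and a single called motif can be a false call. The simulated summit and flank windows had the same base frequencies, while the real ones had a GC content of 35.3% and 43.2%. False calls from a difference in base composition were therefore not simulated and can be more frequent than in the simulation. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.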

Results

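The series measured where the protein CG10669, carrying a GFP tag at its C-terminus, was found along the genome of whole Drosophila melanogaster prepupae. ChIP-seq recovers DNA fragments bound by a protein with an antibody and sequences them, and the prepupa is the stage at the onset of metamorphosis. There were 3 biological replicates of this group and no second condition, so comparisons were made between replicates and between peaks and background positions. The reproducible list held 7248 peaks with a median width of 388 bp and a median signal of 303.8. Sequencing depth was unknown.

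Of the peaks of highest signal, some lay at promoters and others in introns or between genes. The summit ranked 1 lay on 3L at 19590621, 97 bp from a TSS of CG14100, with a relative signal of 81.3 ± 14.9 (SD, n = 3). The peak at Ugalt, a UDP-galactose transporter gene on X, followed with 79.8 ± 13.2 (SD, n = 3). The peak at rdgB, which encodes a phosphatidylinositol transfer protein of photoreceptors, reached 72.7 ± 31.4 (SD, n = 3), a spread that left its order against the 2 peaks above open. The intronic peak in CG11050 had 60.5 ± 6.24 (SD, n = 3), and the intronic peak nearest to cbt, which encodes a zinc finger transcription factor, had 57.6 ± 6.38 (SD, n = 3).

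Further promoters among the 25 peaks of highest signal belonged to Hibch, a gene of valine breakdown (55.6 ± 31.6, SD, n = 3), and PNPase, a mitochondrial RNA-processing enzyme gene (55.0 ± 3.62, SD, n = 3). The promoter peak of larp, which encodes a La-related RNA-binding protein, had 50.2 ± 7.56 (SD, n = 3), and that of CG18549 had 50.7 ± 7.39 (SD, n = 3). Wdr24, which encodes a subunit of the GATOR complex upstream of TOR signalling, had 49.7 ± 21.8 (SD, n = 3). Lk6, a kinase gene whose product acts on the translation factor eIF4E, carried an intronic peak of 48.3 ± 3.55 (SD, n = 3). Chro, which encodes the chromodomain protein Chromator, had a promoter peak of 48.0 ± 4.59 (SD, n = 3) on 3L from 22878682 to 22879128. The summit at 15229535 on 3R lay 127 bp from a TSS of the arginine methyltransferase gene Art3 and 130 bp from that of the mitochondrial ribosomal protein gene mRpS10, with 46.8 ± 7.03 (SD, n = 3). The peak at mRpL41 had 45.8 ± 24.2 (SD, n = 3), and the peak shared by CenG1A and mRpS23 had 47.0 ± 11.9 (SD, n = 3). Peaks at Hsp27, a small heat shock protein gene, and scb, an integrin alpha subunit gene, had 41.3 ± 4.54 and 40.5 ± 5.23 (SD, n = 3). The remaining peaks of this set lay nearest to CG32772, HmgZ, CG13921, CG31145, CG31668 and the non-coding RNA genes lncRNA:CR44619 (with 2 peaks) and lncRNA:CR46035, at 38.6 to 53.4.

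The 7248 reproducible peaks were compared with each replicate's list of the same length to ask which sites every replicate held. All 3 replicates held 4838 of them (66.7%), and shifted positions gave a mean of 1.28%. The reproducible peaks were called from the pooled reads of the same 3 replicates, so an excess over shifted positions was built in and no p-value is given for it. Single replicates held 85.9%, 82.8% and 85.4%, a mean of 84.7 ± 1.66% (SD, n = 3). A further 1556 peaks were held by 2 replicates, 796 by 1 and 58 by none. In the full candidate lists, 6782 peaks (93.6%) were found in all 3 replicates. Recovery in all 3 lists fell from 98.5% in the 10% of peaks with the highest signal to 2.90% in the 10% with the lowest. Each replicate list was cut at 7248 peaks, so peaks near the cut could drop out through small changes of rank, and a fall was built in. Some strong peaks were missing from replicate 1. The promoter peak of Cp190, which encodes an insulator protein, had rank 137 in the pooled list and ranks 201 and 362 in replicates 2 and 3, with no candidate summit of replicate 1 within 200 bp. The same held for the Hsp83 promoter peak, at rank 722 in the pooled list and ranks 816 and 475 in replicates 2 and 3.

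**Figure D1:**
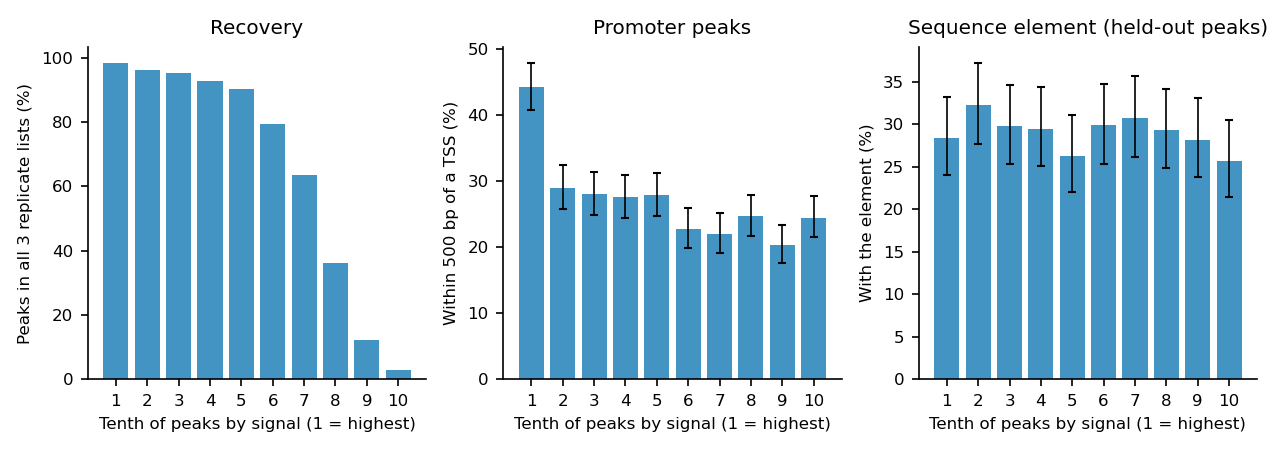
Shares of peaks (%, vertical axes) in 10 equal bins of peaks ordered by signal (horizontal axes, 1 = highest): recovered in all 3 replicate lists (left), within 500 bp of a protein-coding TSS (middle), and with the 16 bp sequence element among even-ranked peaks (right). Error bars in the middle and right panels are 95% Wilson intervals. Recovery falls from 98.5% to 2.90%, the promoter share is highest in bin 1 at 44.3%, and the element share stays between 25.7% and 32.2%. A fall of recovery is built in, since the replicate lists are cut at the length of the reproducible list.

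Replicates 2 and 3 shared 80.7% of their lists, while replicate 1 shared 74.9% with replicate 2 and 74.6% with replicate 3. The mean over the 3 pairs was 76.7 ± 3.47% (SD, n = 3), against 2.16% for shifted positions (permutation p = 0.01 for each pair, the smallest the shifts can give). Across the 6782 peaks found in all candidate lists, Spearman's rho of the signal was 0.76 between replicates 1 and 2, 0.72 between 1 and 3 and 0.84 between 2 and 3. These values are across peaks, which are not independent replicates. All lists were made against the same control file, and its part in this overlap was not measured.

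Promoters and introns held most of the peaks, and coding exons almost none. Of the 7248 summits, 1963 (27.1%, 95% Wilson interval 26.1 to 28.1%) lay within 500 bp of a protein-coding TSS. Shifted positions gave 11.4%, a difference of 2.37-fold (permutation p = 0.002, the smallest the shifts can give), and the candidates of lowest signal gave 10.8%. The replicate lists held 29.1 ± 2.06% promoter peaks (SD, n = 3). Introns held 3485 summits (48.1%) against 40% for shifted positions, and intergenic positions held 1533 (21.2%) against 27.9%. The candidates of lowest signal had 49.8% in introns and 32.0% in intergenic positions, so the intron excess was not particular to reproducible peaks. Coding exons held 15 summits (0.207%) against 13.8% for shifted positions and 2.39% for the candidates of lowest signal. The 3′ UTRs held 59 summits (0.814%) against 4.56%. Each of these 4 classes differed from the shifted positions with a permutation p of 0.01, the smallest that 200 shifts can give. The 5′ UTRs outside the promoter window held 44 summits (0.607%) against 0.788% (permutation p = 0.129), and other exons held 149 (2.06%) against 1.59% (permutation p = 0.0199).

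**Figure D2:**
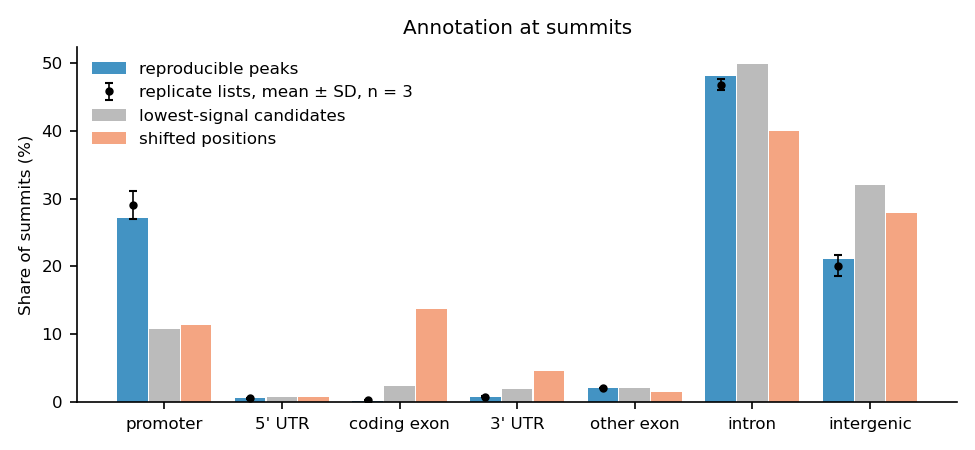
Share of summits (%, vertical axis) in each annotation class (horizontal axis) for the reproducible peaks, the candidates of lowest signal and circularly shifted positions, with points for the mean ± SD of the 3 replicate lists. Promoters held 27.1% of the reproducible summits against 11.4% of shifted positions, and coding exons 0.207% against 13.8%.

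Promoter peaks had a higher signal than distal ones, with medians of 349 and 290 and a ratio of 1.2 (permutation p = 1e-05, the smallest the resamples can give). The ratio was 1.28 in replicate 1, 1.08 in replicate 2 and 1.04 in replicate 3, a mean of 1.13 ± 0.129 (SD, n = 3), so its size was close to the spread between replicates. Among the 10% of peaks with the highest signal, 44.3% were promoter peaks. Away from promoters, 1857 peaks (25.6%) lay more than 5 kb from any TSS. The strongest of these was intergenic on 2R, from 13034992 to 13035561, 11978 bp from CG13323, with a relative signal of 38.4 ± 4.13 (SD, n = 3). The next 4 lay in introns of Raf, the MAP kinase kinase kinase gene (29.7 ± 7.05), CG32486 (29.8 ± 4.52), dnr1 (29.8 ± 4.30) and dpp, the BMP ligand gene (28.0 ± 2.69, each SD, n = 3).

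Peaks were spread over all chromosomes, with a small excess on X and few on chromosome 4. X held 1479 peaks (20.4%) against 17.6% of the sequence, a log2 ratio of 0.21 (exact binomial p = 6.01e-10). The replicate lists gave 0.16 ± 0.05 (SD, n = 3). Against the X share of the candidates of lowest signal, 19.6%, the log2 ratio was 0.060 (exact binomial p = 0.0782), so the excess over length was largely present in low-signal candidates as well. Chromosome 4 held 17 peaks, a log2 ratio of −2.10 (exact binomial p = 5.64e-15), with −1.86 ± 0.68 in the replicate lists (SD, n = 3). The ratios were −0.19 on 2R, 0.11 on 3L, −0.10 on 3R and 0.019 on 2L.

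The gene groups fixed in advance were then compared with all other genes. A summit lay at a promoter of 2145 of 13945 protein-coding genes (15.4%), and the replicate lists gave 16.7 ± 1.42% (SD, n = 3). Genes of cytoplasmic ribosomal proteins were bound most often, 57 of 86 (66.3%, log2 odds ratio 3.46), with 65.9 ± 7.57% in the replicate lists (SD, n = 3). Their Fisher's exact p was 1.58e-26, adjusted to 4.11e-25 over 26 lists. The peak of RpL37A on 2L from 5070628 to 5071125 had the highest relative signal, 34.5 ± 10.6 (SD, n = 3). RpL32 and RpS27 had 9.58 ± 1.49 and 9.64 ± 2.96 (SD, n = 3), and RpL34b was found in replicates 2 and 3 and not in replicate 1. Mitochondrial ribosomal protein genes were bound in 17 of 73 cases (23.3%, adjusted exact p = 0.156, and 0.0440 with canonical TSSs only), and 4 of these peaks (mRpS10, mRpL41, mRpS23 and mRpL23) had ranks from 15 to 97 in the pooled list.

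Genes of the ecdysone response, the steroid signal of metamorphosis, were bound in 12 of 22 cases (54.5%, log2 odds ratio 2.72, Fisher's exact p = 2.43e-05, adjusted 0.000126). The replicate lists gave 54.5 ± 4.55% (SD, n = 3). Among them, the nuclear receptor gene Eip75B had a peak 19 bp from a TSS with a relative signal of 13.5 ± 1.38, the transcription factor gene Eip93F had 11.9 ± 1.31, and the nuclear receptor gene Hnf4 had 9.82 ± 4.81 (each SD, n = 3). Hr78, another nuclear receptor gene, had a peak in replicates 2 and 3 only. Notch pathway genes were bound in 9 of 23 cases (39.1%, log2 odds ratio 1.85, adjusted exact p = 0.0185), including the E(spl) complex genes E(spl)mdelta-HLH (13.1 ± 8.17), E(spl)m3-HLH (13.2 ± 8.38) and E(spl)m7-HLH (12.4 ± 1.97, each SD, n = 3) and the gamma-secretase gene aph-1. The Notch result did not pass without replicate 2 (adjusted exact p = 0.101) or 3 (adjusted exact p = 0.108), with a TSS window of 250 bp (0.112), in the stricter peak set (0.0595) or with peaks recovered in all 3 replicates (0.0788). Its log2 odds ratio was 1.54 to 1.78 in these settings. When only genes with a pooled candidate within 500 bp were used as background, the ribosomal protein genes still passed (log2 odds ratio 2.77, adjusted exact p = 5.45e-09), while ecdysone response genes (0.92, adjusted exact p = 0.543) and Notch genes (0.77, adjusted exact p = 0.732) did not.

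Other groups were bound less often than the remaining genes. None of 96 cuticle protein genes was bound, which allows a share of up to 3.13% (adjusted exact p = 1.29e-06). One of 120 odorant and gustatory receptor genes was bound, Gr77a (0.833%, adjusted exact p = 5.92e-07). Transfer RNA genes were bound in 23 of 290 cases (7.93%, adjusted exact p = 0.0141), with tRNA:Tyr-GTA-1-8 at 21.5 ± 3.04 (SD, n = 3), although reads can be shared between copies. The tRNA result did not pass with a TSS window of 1000 bp (adjusted exact p = 0.269) or with canonical TSSs only (adjusted exact p = 0.149). None of 111 replication-dependent histone genes was bound (up to 2.70%, adjusted exact p = 1.86e-07), and this multi-copy array is uncertain for the same reason. With candidate genes as background, cuticle and tRNA genes remained below the other genes, the receptor genes did not pass (adjusted exact p = 0.365) and the histone genes were not tested.

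**Figure D3:**
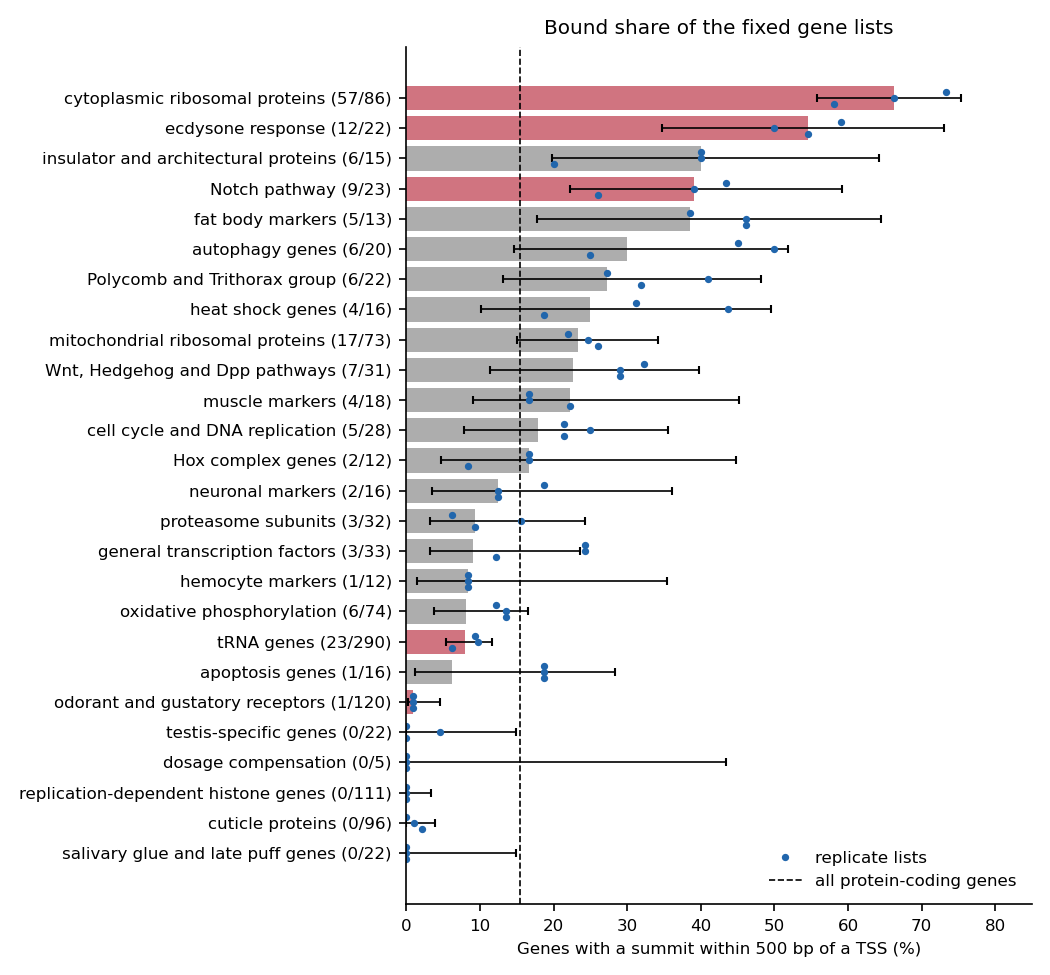
Share of genes with a reproducible summit within 500 bp of a TSS (%, horizontal axis) for 26 gene lists, with bound and total members in brackets; error bars are 95% Wilson intervals, blue points the 3 replicate lists, red bars the lists with an adjusted p under 0.05, and the dashed line the 15.4% of all protein-coding genes. Cytoplasmic ribosomal protein genes reach 66.3%.

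The other 19 lists did not pass the adjusted test. Insulator and architectural protein genes were bound in 6 of 15 cases (40%, adjusted exact p = 0.0613), among them Chro, Cp190, Dref, the gene of the DRE-binding factor, and M1BP. The list passed in the stricter peak set (adjusted exact p = 0.0379). Its log2 odds ratio of 1.91 fell to 1.15 without replicate 2 (adjusted exact p = 0.376) and 1.13 without replicate 3 (0.443). With candidate genes as background it was 0.87 (adjusted exact p = 0.761). Fat body marker genes were bound in 5 of 13 cases (38.5%, adjusted exact p = 0.0908), with the lipin gene Lpin at 31.0 ± 7.81 (SD, n = 3), and the call depended on the setting. It passed without replicate 1, 2 or 3 (adjusted exact p = 0.0447, 0.0384 and 0.0410), with a TSS window of 250 bp (0.0405) and with peaks recovered in all 3 replicates (0.0287). The peak sets chosen by recovery overlap, so their passes are not independent of each other. It did not pass in the stricter peak set (adjusted exact p = 0.256), with a TSS window of 1000 bp (0.0696), with canonical TSSs (0.410) or with candidate genes as background (0.732). Autophagy genes were bound in 6 of 20 cases (30%, adjusted exact p = 0.204), including Atg4b, which shares its peak with Hibch, Atg2 and Atg17, and the list passed in the stricter peak set (adjusted exact p = 0.0378). Polycomb and Trithorax group genes were bound in 6 of 22 cases (27.3%, adjusted exact p = 0.234). Within this group ph-p, a Polycomb repressive complex gene, had 35.5 ± 3.72, the remodeller gene brm 17.9 ± 6.60, the histone methyltransferase gene E(z) 10.8 ± 4.18, and Trl, the GAGA factor gene, 8.12 ± 0.564 (each SD, n = 3).

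Heat shock genes were bound in 4 of 16 cases (25%, adjusted exact p = 0.475), with Hsp26 at 6.98 ± 1.93 (SD, n = 3). Genes of the Wnt, Hedgehog and Dpp pathways were bound in 7 of 31 cases (22.6%, adjusted exact p = 0.479, and 0.0374 with a TSS window of 1000 bp), led by the kinase gene sgg at 19.7 ± 3.44 (SD, n = 3). Muscle markers (4 of 18, 22.2%, adjusted exact p = 0.628), cell cycle and replication genes (5 of 28, 17.9%, adjusted exact p = 0.719) and Hox complex genes (2 of 12, 16.7%, adjusted exact p = 1) were near the share of all genes. Neuronal markers were bound in 2 of 16 cases (12.5%, adjusted exact p = 1), with elav at 19.9 ± 1.98 (SD, n = 3). Proteasome genes (3 of 32, 9.38%), general transcription factor genes (3 of 33, 9.09%) and apoptosis genes (1 of 16, 6.25%) each had an adjusted exact p of 0.628, and the single apoptosis gene was the cell death activator hid, at 20.1 ± 1.13 (SD, n = 3). The replicate lists gave 12.1%, 24.2% and 24.2% for general transcription factor genes and 18.8% in each replicate for apoptosis genes, which is above the shares in the reproducible list. Hemocyte markers were bound in 1 of 12 cases (crq, 8.33%, adjusted exact p = 0.798), and oxidative phosphorylation genes in 6 of 74 cases (8.11%, adjusted exact p = 0.204). No bound member was found among 22 salivary glue and late puff genes or 22 testis-specific genes (each up to 13.6%, adjusted exact p = 0.0908, and 0.0446 for the glue and late puff genes with a TSS window of 1000 bp), or among 5 dosage compensation genes (adjusted exact p = 1).

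Head-to-head gene pairs were counted among bound and unbound genes. Of 2145 bound genes, 983 (45.8%) had such a partner, against 3665 of 11800 unbound genes (31.1%), an odds ratio of 1.88 (Fisher's exact p = 4.89e-39). The replicate lists gave 47.6 ± 2.82% (SD, n = 3). The peak shared by Art3 and mRpS10 was of this kind. A single peak can mark both genes of a pair, which raises this odds ratio by itself. With each summit counted only for the gene with the nearest TSS, a count chosen after seeing the data, 602 of 1695 bound genes (35.5%) and 33.0% of unbound genes were in pairs, an odds ratio of 1.12 (Fisher's exact p = 0.0448). Most of the difference was lost in this count, which can in turn undercount genes whose partner lies closer to the peak.

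The sequence at summits was AT-rich. GC content was 35.3% in the summit window and 43.2% in the flanks, a difference of −7.89 percentage points (SE 0.119 over peaks), and −7.40 ± 1.60 in the replicate lists (SD, n = 3). The candidates of lowest signal differed from their flanks by −0.374 points. Of 23 motifs fixed in advance, 8 were more frequent at summits and 7 less frequent, adjusted over the 23. The TATA box was found in 35.7% of summit windows and 20.3% of flanks (log2 ratio 0.81, adjusted exact p = 5.55e-91), and the Mef2 box in 11.8% and 6.31% (0.90, adjusted exact p = 3.60e-29). The GATA motif (34.2% and 27.2%), the Su(Hw) core (0.483% and 0.152%), the CTCF core (0.869% and 0.483%), the DRE (0.938% and 0.524%) and core promoter motifs 1 (0.373% and 0.124%) and 6 (0.386% and 0.152%) were also more frequent. The Pho core (16% and 22.3%), the CAGCTG E-box (6.51% and 9.49%), the CACGTG E-box (1.49% and 2.35%), GAGA (23.5% and 25.7%), AP-1 (1.57% and 2.35%), Zelda (3.63% and 4.43%) and the nuclear receptor motif AGGTCA (3.81% and 4.54%) were less frequent. With flanks matched for GC content, the TATA box no longer differed (log2 ratio 0.024, adjusted exact p = 0.581), nor did the Mef2 box (0.12, adjusted exact p = 0.125), the DRE (0.41, adjusted exact p = 0.213) or the Su(Hw) core (0.27, adjusted exact p = 0.598). Against summit sequence shuffled with its dinucleotides kept, these 4 motifs stayed more frequent, with log2 ratios of 0.20 for the TATA box, 0.34 for the Mef2 box, 1.955 for the DRE and 1.88 for the Su(Hw) core (adjusted exact p at most 0.000163), so the controls differed. With matched flanks GATA became less frequent (−0.080, adjusted exact p = 0.0297), and GAGA (0.35, adjusted exact p = 5.90e-13) and the CAGCTG E-box (0.44, adjusted exact p = 4.85e-05) became more frequent. Pho (−0.48 with unmatched and −0.063 with matched flanks, adjusted exact p = 0.359) and the CACGTG E-box (−0.65 and −0.13, adjusted exact p = 0.598) no longer differed. Zelda (−0.29 and −0.24, adjusted exact p = 0.0949) and AGGTCA (−0.25 and −0.20, adjusted exact p = 0.155) no longer passed at nearly unchanged ratios, and AP-1 stayed less frequent (−0.69). The sets without a replicate were compared with unmatched flanks only. In these sets AP-1 did not pass without replicate 1 (adjusted exact p = 0.0512), 2 (0.0675) or 3 (0.238). The CTCF core (1.69) and core promoter motifs 1 (2.90) and 6 (1.72) remained more frequent with matched flanks. Against shuffled sequence the CTCF core (1.85) and motif 1 (5.26) also stayed more frequent, while motif 6 did not pass (0.87, adjusted exact p = 0.0761). In distal peaks with unmatched flanks, the log2 ratio was 0 for motif 1 and 0.11 for the DRE, against 1.84 and 1.60 in promoter peaks. The CTCF core did not pass in the stricter peak set (0.26, adjusted exact p = 0.714). With unmatched flanks, the CTCF core did not pass without replicate 1 (adjusted exact p = 0.478) or 3 (0.277), motif 1 without replicate 1 (0.177) and motif 6 without replicate 3 (0.0555). In the same sets, the Su(Hw) core did not pass without replicate 1 (adjusted exact p = 0.0512) or 3 (0.249). The DRE did not pass without replicate 1 (adjusted exact p = 0.177) or 2 (0.0829).

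Among 8192 7-mers, 1667 were more frequent at summits and 3385 less frequent. Of the words found in at least 100 summit windows, TACACTG and CACTGAG, which share the core CACTG, had the highest ratios. TACACTG was found in 584 summit windows against a mean of 122.5 flank windows (4.77-fold, adjusted exact p = 8.14e-78), and CACTGAG in 507 against 116.5 (4.35-fold, adjusted exact p = 2.97e-63). The A-rich word AAAATAT was found in 1951 windows against 930 (2.10-fold), and CACACAC, which had the largest deficit in windows, in 407 against 758.

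**Figure D4:**
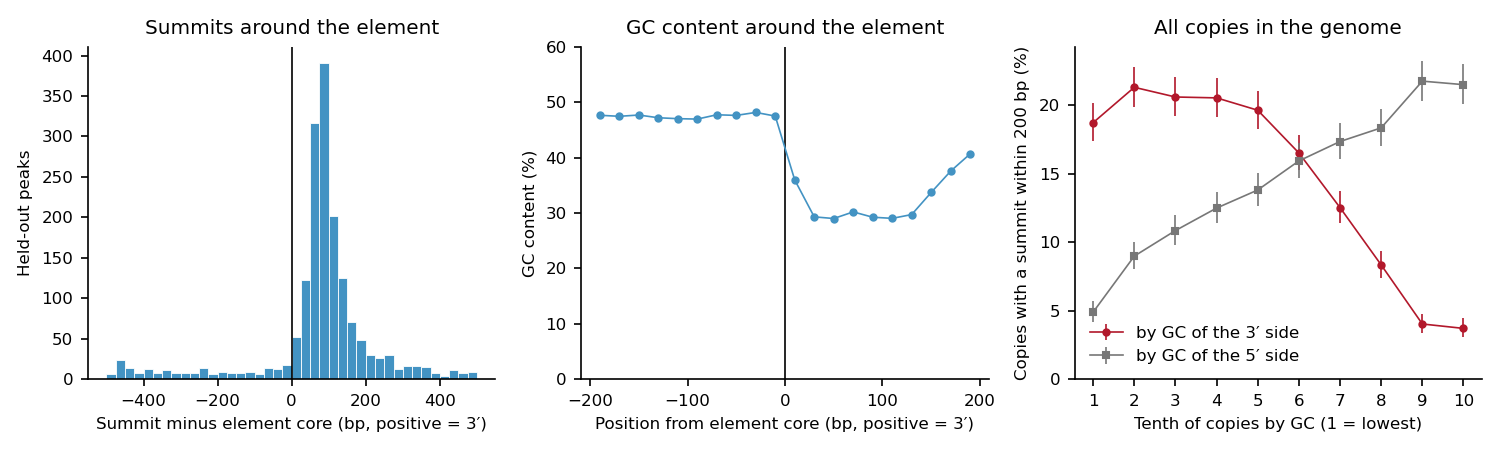
A 16 bp sequence element that extends the CACTG core. Left, number of even-ranked peaks (vertical axis) by the position of the summit relative to the element core (bp, horizontal axis, positive on the 3′ side); middle, GC content (%, mean ± SE) around the core in the 1414 even-ranked peaks with the element within 200 bp; right, share of all genomic copies with a summit within 200 bp (%, with 95% Wilson intervals) in 10 bins of GC content of the 3′ side (red) and of the 5′ side (grey).

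The tagged gene itself showed no peak. CG10669 (FBgn0039329) lies on 3R from 25331363 to 25335243, on the minus strand, and no candidate of the pooled or replicate lists had its summit within 500 bp of the gene. The nearest pooled candidate was 35330 bp away, and the nearest candidates in replicates 1, 2 and 3 were 16287, 29465 and 35284 bp away. Not even low-signal candidates lay nearer. The lists therefore cannot tell an unbound gene from a region that could not yield candidates.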

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

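The alternatives with only peaks recovered in all 3 replicates, canonical TSSs only, GC-matched flanks and nearest TSS only were chosen after seeing the data. The odds ratio of head-to-head pairs fell from 1.88 to 1.12 when each summit counted only for the nearest TSS. Pairwise overlap, promoter share and the ratio of promoter to distal signal kept their direction with p under 0.05 by permutation or exact test under every alternative. Recovery in all 3 replicate lists ranged from 61.3 to 70.1%. It was 73.0 to 75.1% when a replicate was left out, where fewer lists had to hold a peak. The signal correlation ranged from 0.72 to 0.84 when each replicate was left out, and the highest value was without replicate 1. Leaving out a replicate leaves a single pair, so these are the pairwise values given above and no separate check. The log2 X excess was 0.060 (exact binomial p = 0.0782) against the candidates of lowest signal. The number of gene lists that passed fell from 7 to 3 with candidate genes as background, where 21 lists could be tested. Similar numbers of calls could hide different members: without replicate 2 or 3, fat body genes passed in place of Notch genes. The number of motifs more frequent at summits fell from 8 to 5 with windows of 50 bp on each side of the summit, in place of 100 bp. It fell to 4 in distal peaks and to 4 in the stricter peak set, and it was 4 to 7 in the peak sets without each replicate. It rose to 11 with windows of 200 bp on each side and 12 with shuffled sequence, of which 5 and 6 were among the original 8. With GC-matched flanks 8 motifs passed again, but only 3 were among the original 8. On the log2 scale, GAGA changed sign with windows of 200 bp on each side (0.26), shuffled sequence (0.64), promoter peaks (0.017) and GC-matched flanks (0.35), and CAGCTG did so in the same settings (0.13, 0.99, 0.0077 and 0.44). GATA changed sign with shuffled sequence (−0.16) and GC-matched flanks (−0.080), and the nuclear receptor motif in distal peaks (0.021). The cause was not tested. Lists that never passed, such as Hox and muscle genes, also changed sign. Unknown depth limits how weak a site the lists could hold.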

Other observations

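Promoter peaks of ribosomal protein genes differed in sequence from other promoter peaks. The polypyrimidine initiator (TCT) was found in 47 of 57 of these peaks (82.5%) and in 21.2% of 1906 other promoter peaks (Fisher's exact test, adjusted p = 1.50e-20 over 23 motifs). TCT is the initiator of ribosomal protein genes, and unbound promoters of these genes were not compared. The differences can therefore belong to the gene class and do not bear on binding. The CGATA core of BEAF-32 was found in 66.7% and 26.3% (adjusted exact p = 3.47e-09), the DRE in 26.3% and 2.10% (adjusted exact p = 7.38e-11) and core promoter motif 1 in 10.5% and 0.839% (adjusted exact p = 0.000138). The CACGTG E-box (12.3% and 1.89%, adjusted exact p = 0.000787), core promoter motif 6 (5.26% and 0.420%, 0.0124) and the Pho core (28.1% and 14.3%, 0.0236) were also more frequent. The initiator motif TCAGTY was less frequent (5.26% and 18.0%, adjusted exact p = 0.0348).

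The CACTG words extended to a 16 bp element, GTACACTGAGAAAAAA by its most frequent bases, learned on odd-ranked peaks from a word picked over all peaks. In even-ranked peaks it was found within 100 bp of 1050 of 3624 summits (29.0%, 95% interval 27.5 to 30.5%), against 4.72% in flanks, a ratio of 6.14. The even-ranked peaks of the replicate lists, which include sites the element was learned on, gave 27.8 ± 2.64% at summits and 4.88 ± 0.120% in flanks (SD, n = 3). Distal peaks held it in 35.2% of cases, promoter peaks in 11.7%, and the candidates of lowest signal in 10.7%. The element lay at the edge of an AT-rich stretch. In 1414 even-ranked peaks with the element within 200 bp, GC content was 47.5% from 20 to 120 bp on its 5′ side and 29.3% on its 3′ side, a difference of −18.2 points (SE 0.293). Genomic copies without a summit had part of this asymmetry, with 44.2% on the 5′ side and 34.0% on the 3′ side. Of 31051 copies in the genome, 4533 (14.6%) had a summit within 200 bp. This share was 18.7% in the 10% of copies with the lowest GC content on the 3′ side, 21.3% in the next 10% and 3.70% in the 10% with the highest. For the 5′ side it ran the other way, from 4.89% in the 10% with the lowest GC content to 21.5% in the 10% with the highest.

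Of the tests below, those on housekeeping promoters, on a fixed shift of summits and on the element in all ribosomal protein promoter peaks were chosen after the result was seen, as were the GC profile and the genomic copies above. No biological explanation was tested, since the labels give 1 group.

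Ribosomal protein promoters were bound in 57 of 86 cases. Unspecific signal at housekeeping promoters was examined in oxidative phosphorylation and proteasome genes, of which 9 of 106 were bound (8.49%, 95% interval 4.53 to 15.4%). Oxidative phosphorylation genes had 13.1 ± 0.780% in the replicate lists (SD, n = 3). Mitochondrial ribosomal protein genes, left out of this test, were bound in 17 of 73 cases (23.3%). Genes of these lists were thus bound less often than ribosomal protein genes. The lists were chosen after their shares were known, ribosomal protein genes may be transcribed more strongly and expression was not measured here, so unspecific signal stays open. As to peaks of neighbouring genes, the nearest TSS belonged to a ribosomal protein gene for 51 of 57 peaks (89.5%, 78.9 to 95.1%). Most of these peaks were thus not closer to another gene. They had been chosen for lying within 500 bp of such a TSS, which favours this result. The same share was not measured for other genes, so the count cannot decide on this explanation. For the 16 bp element, the even-ranked peaks were counted before the others, and 0 of 24 held it (95% interval up to 13.8%) against 112 of 932 other promoter peaks (Fisher's exact p = 0.100), which left the question open. The count was then widened to all 57 peaks, with 0 holding it (up to 5.26%, interval up to 6.31%, Fisher's exact p = 0.00178), and only this wider count, which includes peaks the element was learned on, argues against it.

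The AT-rich sequence and the element at summits could come from a preference for AT-rich fragments. The candidates of lowest signal had a GC difference of only −0.374 points against −7.89 at reproducible summits, so the difference was not equal at every candidate position. These candidates were picked by their low signal, and such a preference could itself raise the signal of AT-rich sites. The comparison therefore cannot decide on the preference. Against flanks matched for GC content, the element was still 4.27-fold more frequent (3.74 to 4.87), so AT content alone does not account for it. Of 1050 element cores, 0 lay in an annotated transposable element (up to 0.286%), so the counted cores were not copies of annotated ones. Only 15 of all 7248 reproducible summits (0.207%) lay in one, so a count near 0 was likely for any sequence at these summits. Copies that are not annotated were not examined. Whether CG10669 itself or a partner contacts the element stays open.

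Summits lay on the 3′ side of the element in 1328 of 1414 even-ranked peaks (93.9%, 92.5 to 95%), at a median of 82 bp, and the even-ranked peaks of the replicate lists gave 91.7 ± 0.446% and 82 ± 5.57 bp (SD, n = 3). A fixed shift of summits along the genome would give the same side for both strands, but summits lay towards higher coordinates for 93.8% of elements on the forward strand and 5.98% on the reverse strand. Among the 93 peaks whose 5′ side was at least as AT-rich as the 3′ side, 62.4% of summits (52.2 to 71.5%) were still on the 3′ side, against 96.1% of the other 1321 peaks. The 62.4% is no higher than the share in the candidates of lowest signal (730 of 1123, 62.2 to 67.7%), so how far AT content places the summits stays open.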
